A study of Drosophila melanogaster with 2 samples.

How the data were processed

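Chromatin immunoprecipitation with sequencing (ChIP-seq) was done, per the labels, on whole wandering larvae of the third instar and of both sexes from a transgenic Drosophila melanogaster line that expresses Sage with GFP at its C-terminus, with an antibody against GFP. Sage is a basic helix-loop-helix (bHLH) transcription factor best known from the salivary gland. Chromatin was sheared with a Bioruptor sonicator, per the labels. There were 2 samples, biological replicates 3 and 4, which form 1 group, so no comparison between groups was made. The labels number them as biological replicates; whether they came from separate cultures of larvae is not given in the sources used here.

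The analysis started from peak lists, with no reads, so the sequencing depth of each sample is unknown and no value here carries a counting error of reads. Per the text deposited with the lists, each replicate has a long list of peaks and background regions that served as input to the irreproducible discovery rate procedure (IDR, which asks whether regions rank alike in both replicates), the pooled replicates have such a list too, and a last list holds the regions that passed the submitters' IDR threshold. Each list exists on the genome builds dm3 and dm6. The deposited signal of a region is the authors' peak caller's own value for that region, computed against a control alignment per the deposited text; its scaling is not given in the sources used here, so the signal was used only to rank or describe regions within 1 list. The deposited −log10 q-value of a region is also the authors' value and was used only to describe the lists. Aligner, peak caller and their versions are not given in the sources used here. The control library was not analysed here.

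On dm6 the replicate lists held 29999 and 30000 regions, the pooled list 30000 and the IDR list 3312. All 3312 IDR regions were found with the same position and signal in the pooled list, where they were its 3312 strongest regions, down to a signal of 95.7. The IDR list thus equals the pooled list cut at a rank. A region's presence in it does not by itself show that the region ranked alike in both replicates. Of the 3312 IDR regions, 3292 lay on chromosome arms 2L, 2R, 3L, 3R, 4 and X and entered every test on annotation, genes or sequence. The other 20 lay on the mitochondrial genome. No region of the 2 replicates' dm6 lists had the same start and end in both. As median widths were 380 bp in replicate 3 and 390 bp in replicate 4, this could not show whether the data were separate. The lists were treated as separate samples per the labels. Coordinates are dm6, counted from 1. Genes came from Ensembl release 115 (BDGP 6 annotation, without transposable elements), with 13945 protein-coding genes on the arms, and sequence from the RefSeq Release 6 genome. No dm6 region reached beyond the end of its reference chromosome. The dm3 lists were only counted, ranked and overlapped with each other.

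Replicate overlap was the share of replicate 3's 3312 strongest regions that met 1 of replicate 4's by at least 1 bp, set against 1000 random placements on the same chromosomes (a one-sided permutation of positions). Each summit was given 1 class, in the order promoter (within 500 bp of any annotated transcription start site, TSS), coding sequence (CDS), 5' UTR, 3' UTR, intron, other exon and intergenic, and shares were compared with 1000 random placements on the same arms (a two-sided permutation of positions; 0.002 is the smallest p these can give). Peaks per arm were compared with 1000 draws over the pooled arm length including Y (a two-sided permutation of positions), with Benjamini-Hochberg adjustment over the arms. A protein-coding gene was called bound when an IDR summit lay within 1 kb of any of its TSSs. For 25 gene lists, bound shares were compared with all other protein-coding genes on the same arms by Fisher's exact test (two-sided, Benjamini-Hochberg over the 25 lists). All planned members were found. The older symbols Eip71CD (MsrA) and Eip55E (Cth) of the ecdysone list were matched through the RefSeq gene table only after the first results had been seen; without them 11 of 16 members were bound (68.8%, adjusted exact p = 1.5e-05). The strongest signal at bound list genes was compared with that at other bound genes by the difference of medians, with 100000 permutations, for lists with at least 3 bound members. A gene list is a set of genes, not a set of replicates, so these p-values say how far the list stands from other genes in these 2 samples.

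For sequence, 21 motifs were searched on both strands of the window from 50 bp left to 50 bp right of each summit and of windows of the same size centred 500 bp to the left and right. They were 10 E-box classes and any E-box (CANNTG, the site of bHLH factors), a forkhead core (TRTTTRY), a Senseless core (AAATCA), GAGAG, a CREB core (TGACGT), the DRE (TATCGATA), Motif 1, the BEAF core (CGATA), the Zelda site, the nuclear receptor half-site (AGGTCA) and the TATA box (TATAAA). The exact McNemar test used 1 flank per peak, its side drawn at random; the control shares printed are the mean of both flanks. All 2080 6-mers (strands merged) were screened the same way against the drawn flank. The 823 strongest and the 823 weakest peaks were compared by Fisher's exact test. Intervals are 95% exact binomial for shares and 95% Wald for paired differences, and cover sampling of peaks or genes alone.

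The gene lists, motifs, most tests and most alternatives were fixed before the data were examined, and so was the rule for the genes named: the gene with the nearest protein-coding TSS for the 20 strongest peaks, all members of the 3 salivary gland lists, up to 4 bound members with the highest signal of each other list, the 5 genes with most summits within the gene or 1 kb of it, and the 5 motifs and 5 6-mers with the lowest p. The test of upstream against downstream summits was not among the tests fixed beforehand. It was an exact binomial test against equal shares on both sides. Alternatives were each replicate's own 3312 strongest regions in place of the IDR list (the setting without the other replicate), the strongest 1646 peaks, other distances, overlap rules, windows and controls, among them the flanking window 300 to 1000 bp away with the closest GC content, and the dm3 lists. Matching on the number of TSSs, random positions matched on GC content, distal peaks and the 823 strongest with GC-matched windows, the ecdysone list against housekeeping and ribosomal protein genes (an exact test within classes of the number of TSSs), counts without the mitochondrial genome, and arms without Y were added after the data were seen.

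The tests of gene lists, signal at list genes, promoter share, arms, replicate overlap, motifs and 6-mers were tested on simulated data. The comparison of strong with weak peaks, the test of upstream against downstream summits and the tests added after the data were seen were not. With binding drawn at random over 13945 genes, 0.2% of lists were called, and a list the size of the ecdysone list bound at a rate of 70 percent was called in 100% of 100 runs. With nothing planted, 0 of 21 motifs and 0 of 2080 6-mers were called, and 20 of 20 planted 6-mers were recovered. Both sides were random windows, without the GC difference between summits and flanks, so calls due to that difference were not simulated. Nor did the simulated binding of genes depend on the number of TSSs. A planted promoter share of 48.1% was measured as 48.5%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.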

Results

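The binding of GFP-tagged Sage was mapped in whole wandering larvae of the third instar, the stage at which the salivary gland has made its glue proteins and ecdysone drives the start of metamorphosis. The data were 2 biological replicates, numbered 3 and 4, each with a list of about 30000 regions on dm6, and 3312 regions that passed the submitters' IDR threshold, here called IDR peaks. Median signal, the authors' own value per region, was 21.6 over replicate 3's list and 23.3 over replicate 4's. The IDR peaks carry the signals of the pooled list, whose median was 39.0, and their own median was 136. Read depth is unknown, and every signal or rank below is a single value per list.

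None of the 20 strongest peaks had a glue gene or another member of the salivary gland lists as its nearest gene. The strongest of the 3292 peaks on chromosome arms (signal 1450, 2L 6612384 to 6612874) was in an intron of CG11050, 990 bp from a TSS, and was the strongest region on an arm in each replicate's list. The next was at the promoter of Ugalt, the Golgi UDP-galactose transporter (signal 1312, X 2703717 to 2704058, 44 bp from the TSS). It was followed by promoter peaks of CG14100 (1265), PNPase, which encodes a polynucleotide phosphorylase (1200), and CG18549 (1179). The other 15 of the 20 strongest peaks had as nearest protein-coding TSS that of eEF1gamma, cbt, CenG1A, CG1888, Lk6, Hsp27, CG9147, Gapdh2, osa, CG4004, Chro, Tcs5, ph-p, Tina-1 and CG32772, with signals down to 867. Among them were genes for a small heat shock protein (Hsp27, signal 999.7, 3L 9383743 to 9384059, 133 bp from the TSS), a glycolytic enzyme (Gapdh2, 965), and the chromatin proteins Chromator (Chro, 918) and Polyhomeotic (ph-p, 904). Of the 20 peaks, 14 were promoter peaks, 4 lay in introns and 2 in non-coding exons. The peak assigned to eEF1gamma was 5772 bp from that gene's TSS and 162 bp from the TSS of the non-coding gene lncRNA:CR31044, and those assigned to osa and CG4004 were 13951 and 6056 bp away. The peak assigned to cbt (signal 1110) was 1357 bp from its TSS and lay in an intron, inside the gene ush. Among the regions on arms, all 20 were within the first 25 of replicate 3's list and the first 22 of replicate 4's. Ranks given below count all regions of a list, of which 15 of replicate 4's and 4 of replicate 3's lay on the mitochondrial genome.

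The replicates shared most of their strong regions. Of the 3312 strongest regions of replicate 3, 1953 (59.0%) met one of replicate 4's 3312 strongest, where random placements gave 1.78% on average and at most 2.63% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Of the 3312 IDR regions, 1926 (58.2%) met one of the 3312 strongest regions in each of the 2 replicates. Of the peaks on arms, 3181 had a region in both replicates' full lists, 82 had none in replicate 3 and 29 had none in replicate 4. Across those 3181 peaks, which are not independent replicates, the signals of both replicates gave a Spearman coefficient of 0.450 and a Pearson coefficient of 0.583 on the log2 scale.

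Sage-GFP summits lay mainly just upstream of genes, in introns and between genes, and almost never in coding sequence. Promoters held 1557 of the 3292 summits (47.3%, 95% interval 45.6 to 49.0), 3.50 times the 13.5% of random placements (two-sided permutation p = 0.002, the smallest the placements can give). Introns held 37.2% (random 39.3%, permutation p = 0.018), but with promoters of 200 bp they held 44.2%, more than at random (41.4%, p = 0.002). The share was 12.8% in intergenic sequence (random 27.5%, permutation p = 0.002). A single summit fell in coding sequence outside promoters, in bif (X 11681723 to 11682112, signal 129), a share of 0.030% against 13.9% of random placements (permutation p = 0.002); it is named because it was the one case, after its value was seen. In coding sequence lay 0.121% of the summits of replicate 4's own strongest regions and 0.181% of those of replicate 3's. The share in 3' UTRs was 0.972% against 4.39% (permutation p = 0.002), and it was 1.03% in replicate 4's regions and 2.02% in replicate 3's. Within 500 bp of the nearest protein-coding TSS, 1175 summits lay upstream and 265 downstream, so 81.6% were upstream (95% interval 79.5 to 83.6; exact binomial p = 8.9e-137). The 100 bp directly upstream held 410 summits and the next 100 bp 388, against 43.0 ± 6.8 and 37.3 ± 5.8 at random (mean ± SD of 100 placements).

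**Figure D1:**
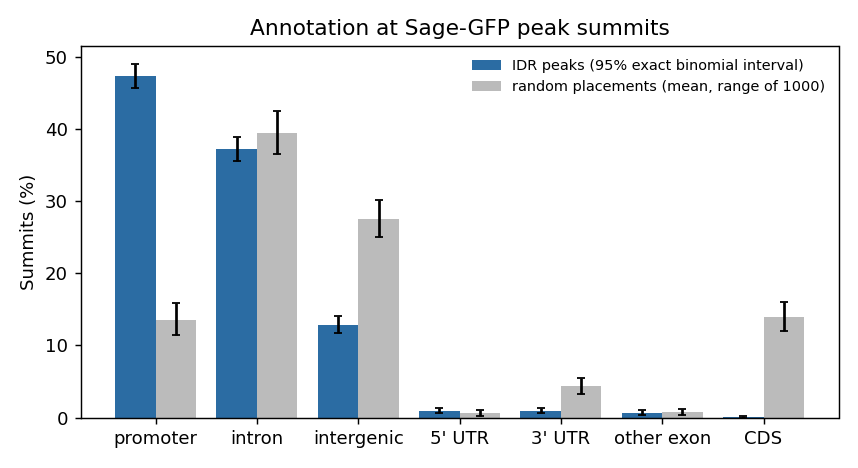
Share of the 3292 peak summits in each annotation class (blue, % of summits, with 95% exact binomial intervals) and of random placements on the same arms (grey, mean with the range of 1000). Promoters held 47.3% of summits against 13.5% at random, and coding sequence 0.030% against 13.9%.

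**Figure D2:**
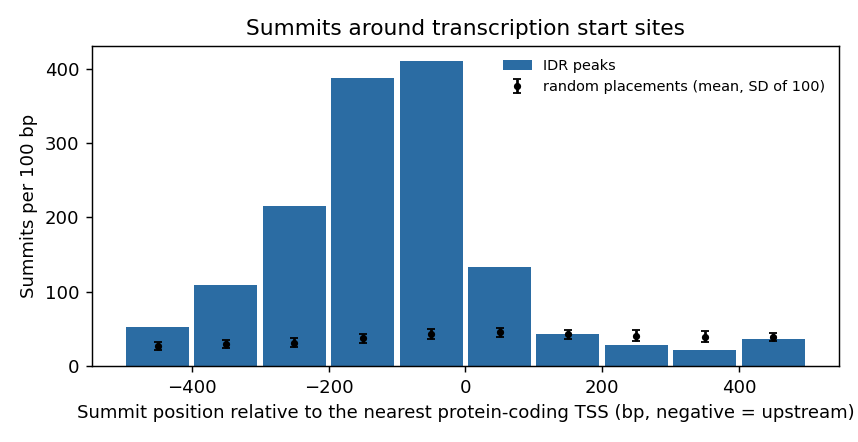
Number of peak summits per 100 bp (vertical axis) by their position relative to the nearest protein-coding TSS (horizontal axis, bp, negative upstream). Points show the mean and SD of 100 random placements. The bars peak at 410 and 388 summits in the 200 bp upstream of the TSS.

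Peaks were spread over all large arms. Density was highest on 3L, with 27.4 peaks per Mb (770 peaks, 1.14 times the random mean, adjusted permutation p = 0.007), and, apart from Y, lowest on the small chromosome 4, with 14.1 per Mb (19 peaks, 0.591 times, adjusted p = 0.033). Arms 2L (25.6 per Mb), 3R (24.5), 2R (23.3) and X (22.3) did not pass the threshold, with adjusted permutation p from 0.109 to 0.492. The 3L call was lost in the strongest 1646 peaks (13.2 per Mb, 1.10 times, adjusted permutation p = 0.080) and against draws of weaker pooled regions (1.04 times, adjusted permutation p = 0.362). Arm 2L passed, above random, in the strongest 1646 peaks (1.16 times, adjusted permutation p = 0.028) and in replicate 4's list (1.10 times, 0.042), and 2R passed against weaker pooled regions (1.12 times, 0.012). The chromosome 4 call was lost in each replicate's own strongest regions: replicate 4 gave 15.6 per Mb (adjusted permutation p = 0.078) and replicate 3 gave 23.7 per Mb (adjusted p = 1). That call stayed in the strongest 1646 peaks (0.374 times, adjusted permutation p = 0.014) and against draws of weaker pooled regions (0.241 times, 0.012). It also stayed with Y left out of the draws (0.569 times, adjusted permutation p = 0.024). The X had 19.8 regions per Mb in replicate 4's list (adjusted permutation p = 0.0047, fewer than at random) and 24.9 in replicate 3's (adjusted p = 0.517). With Y left out of the draws, the 22.3 per Mb of the IDR peaks on X passed (fewer than at random, adjusted permutation p = 0.024). No region of these lists lay on Y.

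In all, 2010 of 13945 protein-coding genes (14.4%) had a summit within 1 kb of a TSS. Over the 3 lists of salivary gland genes 5 of 34 were bound (14.7%). None of the 12 glue genes was bound (0%, 95% interval 0 to 26.5%; adjusted p = 0.422 by Fisher's exact test, which could not tell this from the 14.4% of other genes). For Sgs7, Sgs8, Eig71Ee, ng1, ng2, ng3 and ng4 the pooled list had no region within 1 kb. For Sgs1, Sgs3, Sgs4, Sgs5 and Sgs5bis it had weaker regions, with signals of 61.0, 47.4, 72.3, 95.5 and 95.5. Sgs5 (3R 17595362 to 17596112) and its neighbour Sgs5bis share one such region, which at rank 3325 of the pooled list was just below the weakest IDR peak. It ranked 2207 in replicate 3 and 6663 in replicate 4, so 2 of 12 glue genes (16.7%) were bound in replicate 3's own strongest regions and 0 in replicate 4's.

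Among 14 transcription factors of the salivary gland, 4 were bound (28.6%, adjusted exact p = 0.315). They were Xbp1, a regulator of secretory capacity (signal 223, summit 174 bp from the TSS, 2R 21143371), fkh, the forkhead factor of the gland (142, 3R 28585507), CrebA, a regulator of secretory pathway genes (116, 3L 15535265), and da, the common bHLH partner (116, 39 bp from the TSS, 2L 10388066). The fkh peak ranked 661 in replicate 4 and 18191 in replicate 3, while Xbp1 ranked 593 and 715, and da ranked 2944 and 2717. Of the others, sage itself, hkb and toe had no region within 1 kb in any dm6 list. Senseless (sens) and rib had none in the pooled list, and Scr, exd, hth, trh and eyg had pooled regions with signals from 62.4 to 93.4. One of 8 salivary gland enzyme and secretion genes was bound (12.5%, adjusted exact p = 1): ps (pasilla), with 4 summits within 1 kb of a TSS and a signal of 188. The genes PH4alphaSG1, PH4alphaSG2, wbl, pip, Papss, sll and CG14756 had no IDR peak.

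Genes of the ecdysone response were bound far more often than other genes. Of 18 listed genes, 12 had a peak (66.7%, 95% interval 41.0 to 86.7) against 14.3% of other genes, an odds ratio of 11.9 (adjusted exact p = 7.8e-06). The highest signals were at E23, an ABC transporter gene (297, 2L 3334875 to 3354829), tai, a coactivator of the ecdysone receptor (253), Eip75B, a nuclear receptor of the early response (247, 3L 17950953 to 18064696), and EcR, the receptor itself (244, 2R 6087873 to 6169087). These 4 peaks ranked 199, 524, 367 and 1371 in replicate 3 and 416, 403, 676 and 295 in replicate 4. The share was 72.2% in replicate 4's strongest regions (odds ratio 15.6, adjusted exact p = 3.7e-07) and 55.6% in replicate 3's (odds ratio 6.52, 0.0012). Among genes with a pooled region within 1 kb it was 75% against 33.0% of other genes, with a lower odds ratio of 6.09 (adjusted exact p = 0.0051).

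Ribosomal protein genes and general housekeeping genes were also bound more often. Of 92 ribosomal protein genes 31 were bound (33.7%, 95% interval 24.2 to 44.3; odds ratio 3.05, adjusted exact p = 2.6e-05), led by RpL32 (signal 270), RpL7 (267), RpL24 (257) and RpL27 (241). Their share was 39.1% in replicate 4's list (odds ratio 3.89, adjusted exact p = 5.0e-08) and 27.2% in replicate 3's (odds ratio 1.95, 0.027). Of 18 housekeeping genes 7 were bound (38.9%; adjusted exact p = 0.039), led by Gapdh2 (965), Act5C (376), RpL32 (270) and Pgk (245), whose peak had no region in replicate 3. The lists share 3 members. The housekeeping call was lost with TSSs within 500 bp (33.3%, odds ratio 3.69, adjusted exact p = 0.054) and in the strongest 1646 peaks (27.8%, 4.52, 0.067). It was also lost among genes with a pooled region within 1 kb (63.6%, 3.55, 0.175). The odds ratio with all peaks was 3.79. The call passed in replicate 4's list (50%, adjusted exact p = 0.0022) and replicate 3's (44.4%, 0.022). It also passed with TSSs within 2 kb (50%, 0.0074) and with only the nearest gene per summit (33.3%, 0.044). In 5.72% of random lists matched on the number of TSSs as many genes were bound. In the strongest 1646 peaks, 12.0% of ribosomal protein genes were bound and the call was lost (adjusted exact p = 0.576).

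Chemoreceptor, Cpr cuticle protein and odorant-binding protein genes were bound less often than other genes. Of 179 chemoreceptor genes 1 was bound, Or9a (0.559%; adjusted exact p = 1.1e-09), and in replicate 4's list 2 were (1.12%, 1.4e-08). None of 70 Cpr cuticle protein genes (adjusted exact p = 0.00026) and none of 51 odorant-binding protein genes (adjusted p = 0.0026) was bound. In the strongest 1646 peaks both counts stayed at 0, but 7.91% and 7.90% of other genes were bound there and neither call passed (adjusted exact p = 0.0505 and 0.160), while that of the chemoreceptors did (2.0e-05). In replicate 4's own list 1 of 70 Cpr genes was bound (1.43%, adjusted exact p = 0.0023). Cytochrome P450 genes were bound in 6 of 85 cases (7.06%, adjusted exact p = 0.191), with the highest signals at Cyp310a1 (356), Cyp6u1 (313), Cyp28d1 (199) and Cyp9f3 (122), of which the peaks at Cyp28d1 and Cyp9f3 had no region in replicate 4. The P450 genes passed, as bound less often, in replicate 4's list (4.71%, adjusted exact p = 0.027) and with TSSs within 500 bp (3.53%, 0.047), but not in replicate 3's list (10 of 85, 11.8%, 0.507). No member was bound among 25 Osiris genes (adjusted exact p = 0.145), 16 Jonah protease genes (0.315) or 10 late genes of the Eig71E cluster (0.626). The Osiris genes passed with TSSs within 2 kb (adjusted exact p = 0.047). Replicate 3's own list gave 1 of 25 Osiris genes (4%), and replicate 4's 1 of 16 Jonah genes (6.25%).

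Markers of other larval tissues did not pass the test. Fat body markers were bound in 4 of 13 cases (30.8%, adjusted exact p = 0.292): Lpin, a regulator of fat storage, had the highest signal of any of these markers (778, rank 23 in replicate 3 and 41 in replicate 4), followed by Apoltp (162), bmm (107) and apolpp (105). Muscle markers were bound in 3 of 17 cases (17.6%, adjusted exact p = 0.921), at Zasp52 (209), Msp300 (181) and Tm1 (105). The single neuron marker bound of 16 was elav (327; adjusted exact p = 0.921), whose peak had no region in replicate 3. The single hemocyte marker of 13 was ush (284; adjusted exact p = 0.921), and none of 15 midgut markers was bound (adjusted p = 0.315).

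The remaining lists did not pass the test. Secretory pathway genes were bound in 6 of 35 cases (17.1%, adjusted exact p = 0.921), led by Sec13 (166), Srp72 (149), Sec23 (119) and Hsc70-3 (110). Genes of O-glycosylation gave 1 of 11 (C1GalTA, 114; adjusted exact p = 1). The endocycle list gave 3 of 22 (13.6%, stg 284, Dp 219, E2f1 158; adjusted exact p = 1), but 7 of 22 in replicate 3's list (31.8%, 0.202) and 5 of 22 in replicate 4's (22.7%, 0.455). Despite its name it also holds general cell cycle genes, stg, CycA and CycB among them. Cell death and autophagy genes gave 5 of 19 (26.3%, adjusted exact p = 0.344), led by Diap1 (362), hid (156), Atg18a (136) and Atg9 (119). Their share was 36.8% in replicate 3's list (adjusted exact p = 0.085), and with TSSs within 2 kb they passed, with 8 of 19 bound against 17.7% of other genes (42.1%, 0.041). Imaginal disc regulators gave 3 of 18 (16.7%, Dll 230, sd 138, ey 131; adjusted exact p = 0.921), and 11.1% in replicate 3's list. Vacuolar ATPase genes gave 4 of 33 (Vha100-2 261, Vha14-1 154, Vha44 130, Vha68-2 96.6; adjusted exact p = 1). Rab genes gave 5 of 36 (Rab5 426, Rab14 161, Rab39 132, Rab32 129 among them; adjusted exact p = 1).

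**Figure D3:**
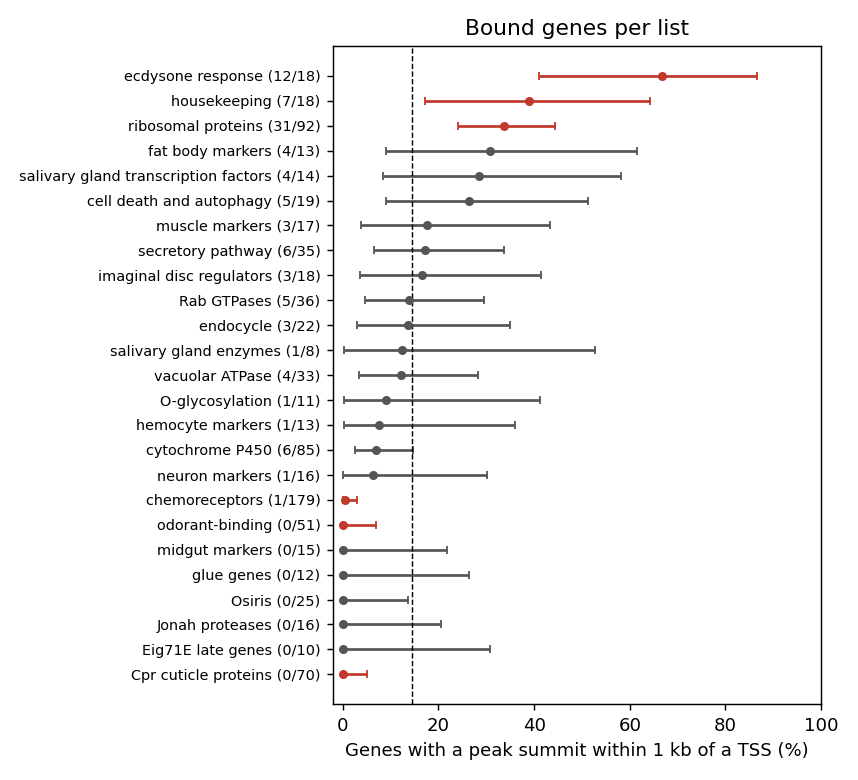
Percent of each list's genes with a peak summit within 1 kb of a TSS (points, with 95% exact binomial intervals; bound and listed genes in brackets). Red marks lists with an adjusted exact p under 0.05 and the dashed line the 14.4% of all protein-coding genes; ecdysone response genes stand highest at 66.7%.

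Among bound genes, signal did not set any list apart. The median signal of the strongest peak per gene ranged from 114.7 for secretory pathway genes to 245 for housekeeping genes. Housekeeping genes had the largest difference, with 245 against 141 in other bound genes (difference 103, permutation p = 0.041, adjusted p = 0.436). That difference was 78.3 in the strongest 1646 peaks, 36.3 with TSSs within 500 bp and -1.92 with TSSs within 2 kb. In the replicates' own lists, whose signals are on other scales, it was 2.70 in replicate 4 (89.8 against 87.1) and -5.33 in replicate 3 (62.3 against 67.7). None of 13 lists passed after adjustment, and 1 had an unadjusted permutation p under 0.05.

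Several regulators carried many summits over their length. Eip75B (114 kb) and sbb, which encodes the corepressor Scribbler (79.1 kb, 2R 18278198 to 18357296), had 16 summits each in the gene or within 1 kb, where the genome average would give 2.85 and 1.99. The others of the 5 highest were Tet (15 summits, 3L 2786207 to 2879158), Tlk (13, 69.8 kb) and shn (13, 58.3 kb).

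The summits were rich in A and T, and E-boxes as a whole were not enriched at them. GC content was 34.7% in the window of 50 bp on either side of the summits, 42.9% in the flanks tested and 42.3% in random windows. In weaker pooled regions it was 35.8%, so the low GC content was largely shared by regions outside the IDR list. The TATA box sequence was present at 21.8% of summits and 11.4% of flanks (adjusted exact p = 8.2e-30), the forkhead core at 36.3% and 24.8% (adjusted p = 1.4e-23), and the BEAF core at 16.2% and 11.6% (adjusted p = 3.3e-06). Any E-box was present at 35.4% of summits and 40.3% of flanks (adjusted exact p = 3.4e-06), and the CAGGTG class at 1.61% and 4.18% (adjusted p = 7.1e-10). In all, 6 of 21 motifs were more frequent and 7 less frequent at summits, and none of the 10 E-box classes was more frequent against these flanks. With flanks matched on GC content (35.6%), the lower E-box share was no longer past the threshold (35.4% against 37.0%, adjusted exact p = 0.307). The lower share of the CAGGTG class was not past it there either (a difference of -0.395 percentage points, adjusted exact p = 0.395). In that setting the TATA box (21.8% against 17.3%, adjusted exact p = 1.2e-05), the forkhead core (36.3% against 32.8%, adjusted p = 0.0074) and the BEAF core (16.2% against 12.7%, adjusted p = 0.00039) stayed more frequent. At the 1735 summits more than 500 bp from any TSS, with the same control, all 3 calls were lost (TATA box 21.6% against 18.2%, adjusted exact p = 0.081; forkhead core 36.9% against 33.5%, 0.153; BEAF core 13.1% against 12.6%, 0.749). The BEAF call was also lost in the strongest 1646 peaks with plain flanks (13.8% against 11.1%, adjusted exact p = 0.122). The E-box class CAGCTG, at 4.80% of summits and 4.85% of plain flanks (adjusted exact p = 0.509), was more frequent than in GC-matched flanks (3.28%, 0.0063) and than in weaker pooled regions (3.16%, 0.0056). The classes CAAATG (9.08% against 11.4%, adjusted exact p = 0.0078) and CATATG (3.95% against 5.13%, 0.0498) were less frequent than in GC-matched flanks. CAGCTG was also more frequent at the summits of replicate 4's list than in plain flanks (5.85% against 4.76%, adjusted exact p = 0.013), but not at those of replicate 3's (5.05% against 4.74%, 0.910). Set against weaker pooled regions, the TATA box was at 21.8% and 22.2% (adjusted exact p = 0.865) and the forkhead core at 36.3% and 34.1% (0.197), so neither set the IDR peaks apart from those, while the BEAF core did (16.2% and 12.7%, 0.00089). The CAGGTG class, at 1.61% and 2.25%, did not pass against those regions (adjusted exact p = 0.218).

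The 6-mer screen gave 330 6-mers more frequent and 761 less frequent at summits. The 5 with the lowest p were AAAATA (36.9% of summits, 19.1% of flanks, adjusted exact p = 5.4e-55), AAATAT (32.2% and 15.3%), AATATA (24.7% and 10.1%), TTAAAA (30.7% and 14.7%) and ATTTTA (28.6% and 13.7%). All of the first 20 consisted of A and T alone. With GC-matched flanks, 67 6-mers were more frequent, and 13 of the first 20 consisted of A and T alone. AAAATA was at 36.9% against 30.2% there (adjusted exact p = 4.5e-07). Ahead of it were AGAGAG, with the lowest p (8.96% against 4.34%, adjusted exact p = 9.5e-12), and, among others, GAGAGC (7.11% against 3.31%, 6.5e-11) and ACAGTG (7.90% against 4.01%, 4.5e-09), which are named after their values were seen.

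**Figure D4:**
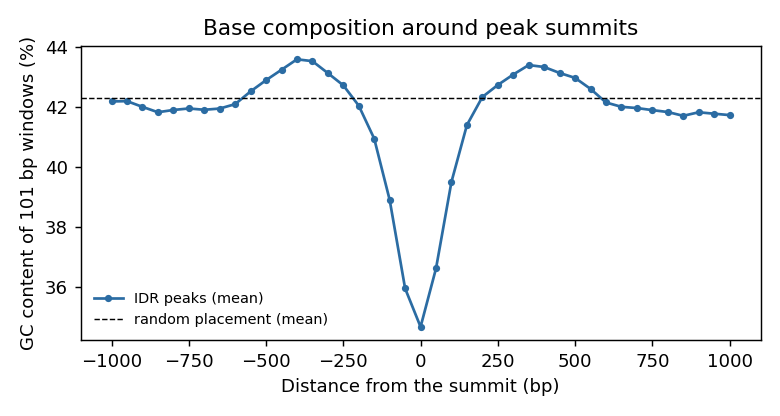
Mean GC content of windows of 50 bp on either side of a position (vertical axis, %; the axis does not start at 0) by distance from the peak summit (horizontal axis, bp) over 3292 peaks. It falls to 34.7% at the summit, and the dashed line marks the 42.3% of random windows.

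Of the 21 motifs, the BEAF core and the DRE passed the comparison of strong with weak peaks, and which motifs passed changed with the peaks used. The DRE (TATCGATA) contains the BEAF core (CGATA), so these calls are not separate. The BEAF core was present at 11.4% of the 823 strongest and 19.2% of the 823 weakest peaks (adjusted exact p = 0.00031), and the DRE, a core promoter element of housekeeping genes, at 0.486% and 2.19% (adjusted p = 0.043). Any E-box was at 35.1% and 34.8% (adjusted exact p = 1), but in replicate 4's list it was rarer at the strongest regions (33.4% against 40.2%, 0.035). In replicate 3's own strongest regions neither the BEAF core (13.5% against 17.2%, adjusted exact p = 0.335) nor the DRE (0.484% against 2.30%, adjusted p = 0.051) passed. The DRE difference was no smaller there (-1.81 percentage points) than in the IDR peaks (-1.70). Within the strongest 1646 peaks, with 411 peaks in each part, both calls were lost (adjusted exact p = 0.424 each). There the BEAF core was at 11.2% and 15.1% (-3.89 points), and the DRE at 0.243% and 1.70% (-1.46). The DRE was also lost with windows of 100 bp on either side (adjusted exact p = 0.269) and with the strongest 1646 against the weakest 1646 (0.412). CAGCTG passed, as rarer at the strongest peaks, within the strongest 1646 (1.22% against 6.81%, adjusted exact p = 0.0010) and in replicate 4's list (2.79% against 7.52%, 0.00036).

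On dm3 the IDR list held 3198 regions. The numbers on dm3 and dm6 were 586 and 603 on 2L, 563 and 589 on 2R, 746 and 770 on 3L, 768 and 787 on 3R, 511 and 524 on X, and 20 and 19 on chromosome 4. The strongest signal outside the mitochondrial genome was 1451 on dm3 and 1450 on dm6, both on 2L.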

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

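The tests of this part were chosen after the results were seen, except that of any E-box against GC-matched flanks in all peaks, which was planned. The study has 1 group, so no explanation by a difference between groups was tested.

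Data outside the comparisons held 20 regions of the dm6 IDR list on the mitochondrial genome, with signals up to 10787, against 4 on dm3 with signals up to 355. On dm6 the highest mitochondrial signal was 9527 in replicate 4 and 95.3 in replicate 3. Weaker regions of the pooled list lay within 1 kb of a TSS of 14 of the 29 genes of the 3 salivary gland lists with no IDR peak (48.3%). Of the other protein-coding genes with no IDR peak 34.0% had such a region, and the difference did not pass (Fisher's exact test, two-sided p = 0.118), so an excess at the salivary gland genes was not shown.

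Any E-box, the site class of bHLH factors taken over all its sequences, was not more frequent at the summits than beside them. The class CAGCTG was more frequent than in flanks matched on GC content (4.80% and 3.28%). Those flanks still had slightly more GC (35.6%) than the summits (34.7%). Against those flanks any E-box differed by -1.58 percentage points (95% interval -3.90 to 0.736); the interval includes 0, so the base composition of the summits stays open as the reason for the lower share. The same test at the 1735 summits more than 500 bp from any TSS gave -2.42 (95% interval -5.59 to 0.752), which argues against an excess of 2 points or more hidden at distal peaks; that bound was set after the data were seen. In the 823 strongest peaks the difference was -0.365 with an interval of -4.96 to 4.23, too wide to exclude dilution by weak peaks. A further candidate explanation, not tested, is that many peaks are places where tagged factors or open chromatin are recovered without a Sage site in the sequence, which a control or another GFP line would be needed to test.

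Summits were almost absent from coding sequence. Random positions matched to the summits on GC content fell in coding sequence in 5.20% of cases (4.31 to 6.11 over 100 draws) against 0.030% of the summits (0.121% and 0.181% in the replicates' own lists), so low GC content alone does not account for the absence. The pooled regions that did not pass the IDR threshold lay in coding sequence in 1.58% of cases (95% interval 1.43 to 1.73), above the IDR peaks but also below the GC-matched positions. The absence was thus shared in part by weaker regions, and the authors' use of the control in calling stays open as a contribution.

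Ecdysone response genes were bound far more often than other genes. Genes with 5 or more TSSs were bound in 53.7% of cases and those with 1 in 10.1%, so the number of TSSs could raise a list's share. Of 10000 random lists matched gene by gene on the number of TSSs, 0.02% had as many as 12 bound genes, and their mean was 5.21. Within classes of 1, 2 to 4 and 5 or more TSSs, the share of 107 housekeeping and ribosomal protein genes would give 7.51 bound ecdysone genes. There were 12 (exact test within classes, two-sided p = 0.031). This argues against binding at the rate of those genes as the whole cause, but the classes are coarse. Most of the 107 were from the list of 92 ribosomal protein genes, so they cannot stand for active promoters in general. Among genes with a pooled region within 1 kb, 75% of ecdysone, 63.6% of housekeeping and 56.4% of ribosomal protein genes were bound. Gene length and expression in the tissue were not tested and stay open.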

How the results depend on the processing

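Arms without Y, distal peaks and the 823 strongest with GC-matched flanks, GC-matched random positions, lists matched on the number of TSSs, the ecdysone list against housekeeping and ribosomal protein genes, and counts without the mitochondrial genome were added after the data were seen; all other alternatives were planned. Of 73 values that answer a comparison, 55 counted as unchanged, and of 534 others 433 did. A test counted as unchanged if it stayed on its side of the threshold and, where it passed in either setting, kept its direction. Where neither setting passed, its direction could differ. Counts were unchanged within a ratio of 1.5, and correlations within the 95% interval of the main value. The promoter share stayed above its control in every setting run, from 31.7% within 200 bp (random 6.15%) to 58.8% within 1 kb (random 23.6%). Set against draws of weaker pooled regions, it was 47.3% and 22.2%, or 2.13 times. Replicate overlap ranged from 50.8% to 61.2%. With each replicate left out, ecdysone genes were bound at 55.6 to 72.2%, and the number of arms past the threshold, Y not counted, was 1 to 3. In those settings the number of lists was 6 to 7, of motifs 11 to 15 and of motifs that differ by signal 0 to 4. There 243 to 370 6-mers were more frequent and 518 to 914 less frequent at summits. In the strongest 1646 peaks the replicate correlation was 0.513, and 2 lists and 5 motifs passed (6 and 13 with all peaks); by signal 1 motif passed, CAGCTG, and the 2 that passed with all peaks, the BEAF core and the DRE, did not. Any E-box there was at -3.52 points (adjusted exact p = 0.060) and no longer passed. By signal the BEAF core was the 1 motif to pass with windows of 100 bp on either side, and the 1 with the strongest 1646 against the weakest 1646. For these and the reversals below the cause was not tested.

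Motif results changed with the control and with the peaks used; a sign is given as turned where the motif passed in either of the compared settings. With GC-matched flanks 67 6-mers were more frequent and 59 less frequent (330 and 761 with plain flanks), any E-box was at -1.58 points and no longer passed, and signs turned for CAGCTG (1.52), CATATG (-1.18), CAAGTG (0.15), CAACTG (0.061) and the Senseless core (-2.67). Against weaker pooled regions 4 motifs passed, and any E-box (0.881), CAGCTG (1.64), CAACTG (0.091), the Senseless core (-0.304) and the TATA box (-0.395) turned. With distal peaks and GC-matched flanks 1 motif passed, any E-box was at -2.42, and CAAGTG (1.44), CAACTG (0.288), the Senseless core (-3.34), the DRE (-0.173) and Motif 1 (-0.115) turned. In the 823 strongest peaks with GC-matched flanks 0 motifs passed, any E-box was at -0.365, and CACGTG (0.243), CAACTG (1.58), the forkhead core (-1.22), the Senseless core (-0.851) and the BEAF core (-1.34) turned. With each replicate left out, CAGCTG ranged from 0.302 to 1.09 points, GAGAG from -4.34 to 5.72, and any E-box in the strongest against the weakest peaks from -6.80 to 0.726. The intron share turned to above random with promoters of 200 bp (44.2%), and arm 2R to above the expectation from weaker pooled regions (23.3 peaks per Mb). Read depth is unknown, so its limits could not be given.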

Other observations

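The values in this part were chosen after the data were seen, although GC-matched flanks for all peaks and each replicate's own list were planned settings. At summits more than 500 bp from any TSS, set against GC-matched flanks, 12 6-mers were more frequent, and the lead was ACAGTG (8.59% of 1735 summits, 3.80% of flanks, adjusted exact p = 6.3e-06), with the related words CAGTGG (5.99% and 2.54%, adjusted p = 0.00019) and CAGTGC (8.30% and 4.03%, adjusted p = 0.00019). ACAGTG was also among the leading 6-mers of all peaks with GC-matched flanks (7.90% and 4.01%, adjusted exact p = 4.5e-09). Under the same control, CAGCTG was the only one of the 10 E-box classes that was more frequent at summits (4.80% and 3.28%, adjusted exact p = 0.0063), and it was at 3.52% and 2.82% (adjusted p = 0.536) at the distal summits. GAGAG, the site of GAGA factor, was at 15.2% and 10.2% (adjusted exact p = 5.4e-09), and it passed against weaker pooled regions (11.4%, 0.00013). It did not pass against plain flanks (14.5%, adjusted exact p = 0.528) or at the distal summits with GC-matched flanks (12.9% and 10.3%, 0.103), but did against plain flanks with windows of 100 bp on either side (29.98% and 26.6%, 0.010).

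The 2 replicates' own strongest regions differed in sequence. GC content at the summits was 33.0% in replicate 3 and 37.0% in replicate 4. GAGAG was at 10.7% of summits in replicate 3, which differed from the flanks by -4.34 percentage points (adjusted exact p = 2.1e-07), and at 19.8% of summits and 14.1% of flanks in replicate 4 (adjusted p = 6.0e-10). On the X lay 17.7% of replicate 3's strongest regions and 14.1% of replicate 4's. The difference between the replicates was not tested, as there is 1 sample of each.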
